A study of Drosophila melanogaster with 6 samples.

How the data were processed

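Gene expression was measured in cells sorted from wing imaginal discs of *Drosophila melanogaster*, the larval epithelia that form the adult wing and the dorsal thorax. Per the labels' protocols, about 200 discs per sample were dissected late in larval life from animals carrying green fluorescent protein (GFP) under regulatory DNA of E(spl)m4, a gene switched on in proneural clusters. Per the same protocols the discs were dissociated with trypsin, cell viability was examined before sorting, and discs without the reporter set the fluorescence threshold. All cells above that threshold formed the GFP-positive samples, and 100000 cells below it formed each GFP-negative sample. The groups and the replicate numbers 1 to 3 were taken from the sample titles, which gave 3 GFP-positive and 3 GFP-negative samples with 1 array each. The labels do not say whether the 3 samples of a group came from separate dissections, so p-values measure the spread between these samples, which may be technical.

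Total RNA was hybridised to an Affymetrix Drosophila genome array with 14010 probe sets, of which 44 are controls. Per the file headers, the deposited intensity of each probe set is the Signal of Affymetrix's statistical algorithm, a linear brightness in arbitrary units. Per the file headers each array was scaled over all its probe sets to a target of 500. The same files give a detection call for each probe set (Present, Marginal or Absent), made with Alpha1 of 0.04, Alpha2 of 0.06 and Tau of 0.015 per the file headers. The deposited detection p-values behind these calls, 1 per probe set, came from the same algorithm per the file headers and were not used here beyond the calls. The deposited series table held intensity values equal to the array files' Signal for all 14010 probe sets of each array, with the same scale, no centring and medians between 125.35 and 151.6. Labelling and amplification steps are not given in the sources used here. The arrays' scaling factors lay between 4.40 and 6.52 and their backgrounds between 58.5 and 69.2 units. The number of arrays, 3 per group, limits the precision of every value.

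Gene names came from the platform annotation table given with the data. It gave 1 gene symbol for 12443 probe sets, several for 327 and none for 1196, and 12394 of the single symbols were updated through their Entrez number with a RefSeq gene table. The named probe sets covered 10844 genes, and probe sets with several symbols were left unnamed. Because the array files name no genome build, no coordinates are printed. Some genes of the wing disc, among them *Notch*, *wg*, *sca* and *chn*, were not analysed here because no probe set carried their symbol.

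The arrays' 2%-trimmed means were equal within rounding, so the signals were used as deposited, without further scaling. Values were transformed as log2(signal + 16), and fold changes on this scale understate the change of dim genes. Probe sets called Present on at least 2 of the 3 arrays of a group were tested, which kept 4943 probe sets and 4202 named genes. The GFP-positive group was compared with the GFP-negative group with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, two-sided). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Differences are GFP-positive minus GFP-negative in log2 units with the standard error (SE) from the limma fit, and signals are given as mean ± SD over 3 arrays. Where a probe set was Present on no array of the dimmer group, its fold is a lower bound with respect to detection alone. Such a bound does not allow for the spread between arrays, so a smaller change remains possible. For *loco* it was 2.38-fold, a log2 difference of 1.25, while the interval of the fit ran from 0.67 to 1.83. The bound sets the brighter group's mean log2 value against the mean of, per array, the higher of the dim probe set's own signal and the lowest signal called Present on that array, which lay between 29.4 and 36.8 units. Where all the dim signals lay above that level the bound is the fitted log2 difference, and since it compares means of log2 values it can exceed the ratio of the mean signals, as for *E(spl)m4-BFM* and *trol*, for which the fitted log2 difference is given in place of a fold.

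Gene lists were tested with limma's camera at a preset correlation of 0.01, with the brightest probe set for each gene. Of 23 lists fixed before the data were examined, the 19 with at least 3 tested genes entered the test, and their p-values were adjusted over these 19. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. A list entry that matched an unrelated gene through a synonym was left out. The genes named in the text were fixed by a rule. They were the 10 highest and the 10 lowest changes with 1 gene symbol whose groups did not overlap and which were Present on all arrays of the brighter group, all tested members of the E(spl) and proneural lists, and up to 4 members of every other list with the smallest p. Other genes are named where the text says so.

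The scripts were tested on simulated data made from the spread of these arrays, in 20 simulated sets of 4943 probe sets with 200 changed. They recovered 55.9% of 2-fold and 98.9% of 4-fold changes, 5.47% of the calls were false, and all recovered changes had the right direction. The simulated values were independent normal draws with the variances of the limma fit. They held no effect of day or lot and no correlation between genes, so these rates may not hold for the real arrays.

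The scanner files placed replicate 1 of both groups on hybridization day 1 and replicates 2 and 3 of both groups on day 2. Per the labels, the arrays came from 3 production lots. The first held GFP-negative replicates 1 and 2 and GFP-positive replicate 1, the second held replicate 3 of both groups, and the third held GFP-positive replicate 2 alone. The pairing of replicate numbers was checked through the correlation of the deviations of same-numbered arrays from their group means, over the tested probe sets. These correlations were 0.402 for replicate 1, 0.102 for replicate 2 and 0.122 for replicate 3. All 3 lay above 0.1, so results with replicate number as a block are given where they changed a call or a count. The correlations do not establish that the numbers pair the samples, since the arrays of replicate 1 were also the only ones of day 1. For replicates 2 and 3 the correlations barely passed, and pairs of opposite groups with different numbers within day 2 had 0.098 and 0.221.

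Alternatives set before the data were examined were no offset and an offset of 64, quantile and median scaling, no filter, Present on all 6 arrays, no intensity trend, blocks for replicate number and lot, the lots that hold both groups, each array left out in turn, the series table, camera with an estimated correlation, fry, the mean of a gene's probe sets, Absent or Marginal in place of Absent, and a fold of at least 2. A block for day, the day 2 arrays alone, the lot of 3 arrays alone, the replicate block with a fold of at least 2, the E(spl) list without *E(spl)m4-BFM* and the splits that part every replicate pair were chosen after seeing the data. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.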

Results

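Sorted cells of the wing disc were compared to find which genes differ between cells that express the E(spl)m4 reporter, a marker of proneural clusters, and the other cells of the same disc. Proneural clusters are the groups of cells from which sensory organ precursors, the founder cells of the fly's bristles and other sense organs, are singled out through Notch signalling. There were 3 arrays of GFP-positive and 3 of GFP-negative cells. The GFP-negative arrays called 5039, 4958 and 4382 of the 14010 probe sets Present (replicates 1, 2 and 3), and the GFP-positive arrays 4321, 4330 and 4541. The mean was 4397 ± 125 (SD, n = 3) in GFP-positive and 4793 ± 358 (SD, n = 3) in GFP-negative cells, a difference with a two-sided exact permutation p of 0.2, where 3 arrays against 3 cannot give less than 0.1. The first principal component (41.4% of the variance) separated the groups, and the second (26.9%) separated the arrays by hybridization day.

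**Figure D1:**
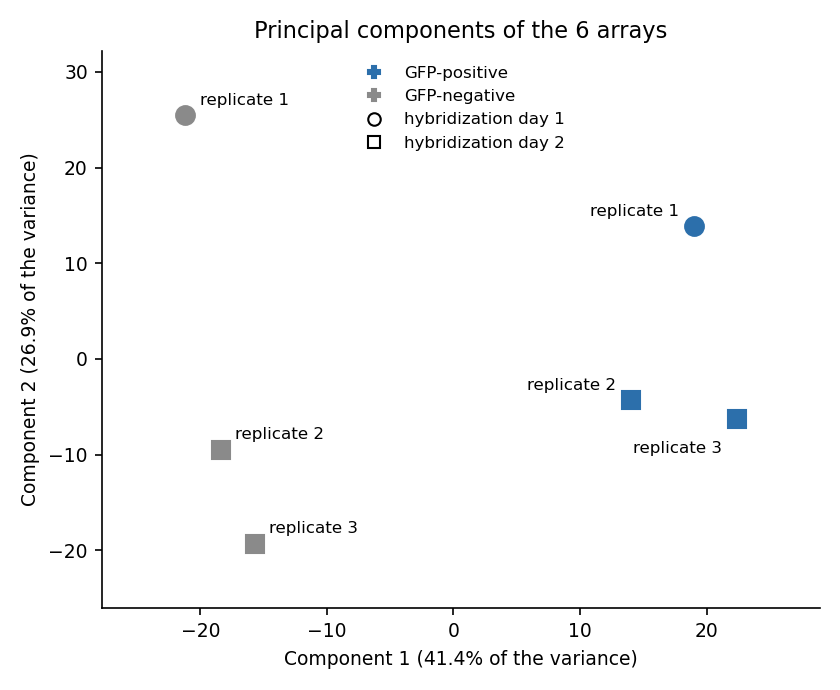
First and second principal components of the 6 arrays over the tested probe sets, with the axes in component units; blue points are GFP-positive and grey points GFP-negative arrays, circles were hybridised on day 1 and squares on day 2. The GFP-positive arrays lie between 14 and 22.4 on component 1 and the GFP-negative arrays between -21.2 and -15.7.

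The gene whose regulatory DNA drove the sorted reporter was higher in GFP-positive cells. *E(spl)m4-BFM*, a Bearded-family antagonist of Notch ligand activation, had a signal of 2353 ± 232 (SD, n = 3) in GFP-positive cells and 236 ± 163 in GFP-negative cells, where no array called it Present. The fitted log2 difference was 3.58 (limma adjusted p = 0.00558), with 2.62 in the day 1 pair and 2.77 without GFP-negative replicate 3. The cells were sorted on this gene's regulatory DNA, so its level checks the sort and is not a separate finding. Other genes known from sensory organ precursors stood beside it. *meru*, which encodes a polarity protein of sensory organ precursors, was at least 14.1-fold higher (adjusted p = 2.05e-05), and *phyl*, an adaptor for degradation of the neural repressor Tramtrack, rose from 139 ± 50.6 to 1321 ± 196 (log2 3.15, SE 0.287, adjusted p = 0.000283).

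Of the E(spl) complex and Bearded family, the Notch target genes that act in lateral inhibition, 9 genes were tested, and 5 rose, 0 fell and 4 did not pass. The 5 were *E(spl)m4-BFM*, *Ocho* (at least 10.6-fold, adjusted p = 0.00558), *E(spl)mdelta-HLH* (log2 2.17, SE 0.272, adjusted p = 0.00165), *E(spl)m7-HLH* (log2 1.62, SE 0.27, adjusted p = 0.00914) and *Brd* (log2 1.48, SE 0.314, adjusted p = 0.0322). Adjusted over the list alone, 6 were higher. The other 4 did not pass. *E(spl)mbeta-HLH* had signals of 8826 ± 1860 and 8819 ± 1960 (log2 0.01, adjusted p = 0.997), *Tom* had a log2 difference of -0.41 (adjusted p = 0.418), *E(spl)m3-HLH* of 0.51 (adjusted p = 0.444) and *E(spl)malpha-BFM* of 0.93 (adjusted p = 0.144, or 0.0473 with the replicate block). The list's median was 1.48 (0.90 with no filter and 0.72 over probe sets Present on all 6 arrays) and its camera adjusted p = 6.02e-07, but adjusted p = 0.122 with an estimated correlation. *E(spl)m4-BFM* and *Ocho* were tested only because the GFP-positive arrays detected them, which favours members that rose. Without *E(spl)m4-BFM*, on whose regulatory DNA the cells were sorted, 4 of 8 rose, the median was 1.2 and the camera p, not adjusted over lists, was 3.02e-06, but p = 0.0601 with an estimated correlation. The call of *Brd* was lost without GFP-negative replicate 1 (adjusted p = 0.0594), 2 (0.0549) or 3 (0.0641) and without GFP-positive replicate 2 (0.112) or 3 (0.127), with lot as a block (0.112), with no filter (0.11) and in the day 2 arrays (0.0516).

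Of the list of proneural and sensory organ precursor genes, 9 were tested, of which 7 rose, 0 fell and 2 did not pass, and adjusted over the list alone all 9 were higher. *insv*, a nuclear corepressor, was at least 6.78-fold higher (adjusted p = 0.000363), *mira*, an adaptor that segregates fate determinants in asymmetric division, at least 6.17-fold (adjusted p = 0.000841), and *cpo*, an RNA-binding protein of the peripheral nervous system, at least 4.92-fold (adjusted p = 0.00313). *cato*, a bHLH protein of the atonal family, rose by a log2 difference of 2.28 (SE 0.378, adjusted p = 0.00887), *siz* by 2.29 (SE 0.418, adjusted p = 0.0161) and *Traf4* by 1.44 (SE 0.281, adjusted p = 0.0223). The proneural gene *sc* itself (log2 1.29, SE 0.351) had an adjusted p of 0.0926, or 0.0383 with the replicate block. The ubiquitin ligase gene *neur* (log2 1.66, SE 0.396) had an adjusted p of 0.0554, or 0.016 with the replicate block, 0.032 with the day block, 0.0288 without an intensity trend and 0.0487 under median scaling. The list had 18 genes on the array. *amos*, *ase*, *ato*, *insc*, *l(1)sc*, *pon*, *pros* and *sens* were Present on no array and *ac* on 1, too few to be tested. *phyl*, *insv*, *mira*, *cpo*, *cato* and *sc* passed the detection filter through the GFP-positive arrays alone, which favours members that rose. The list had a median of 2.29 (1.55 at the lowest under other settings) and a camera adjusted p = 2.52e-16, but adjusted p = 0.0888 with an estimated correlation. Part of what is known of precursor genes, such as *siz*, *Traf4* and *insv*, may come from work on these samples, so the list is not independent evidence of its direction; of the 6 tested members other than these 3, 4 rose. The call of *cato* was lost without GFP-positive replicate 1 (adjusted p = 0.0533) and that of *siz* without GFP-negative replicate 2 (0.0549). The call of *Traf4* was lost without GFP-negative replicate 2 (0.114) or 3 (0.0603) and without GFP-positive replicate 1 (0.103) or 2 (0.0819), and with lot as a block (0.0567). In the day 2 arrays *Traf4* (0.0605), *cato* (0.0646) and *siz* (0.0593) missed the threshold, as they did with no filter (0.0699, 0.052 and 0.052).

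**Figure D2:**
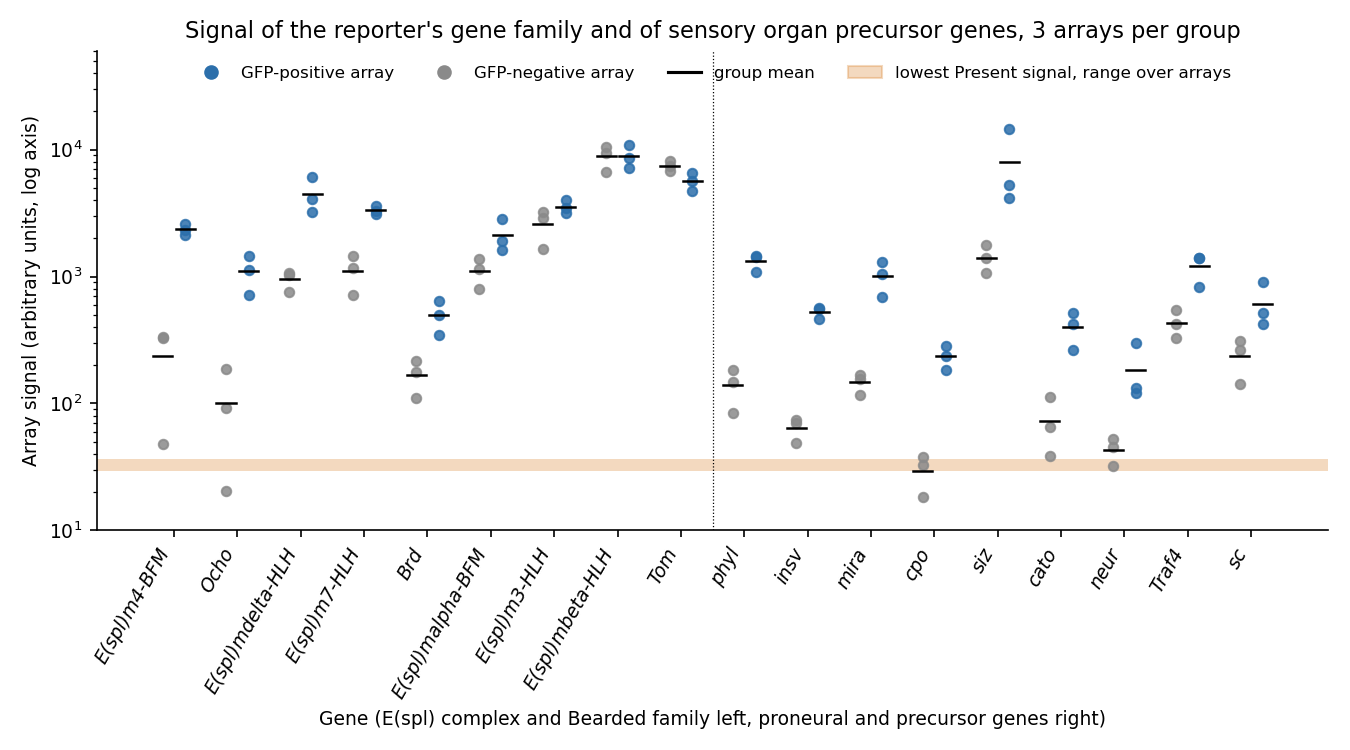
Signal per array (arbitrary units, log axis) of the tested members of the E(spl) and Bearded family, left of the dotted line, and of the proneural and precursor list, right of it; blue points are GFP-positive and grey points GFP-negative arrays, black bars are group means (n = 3), and the band spans the arrays' lowest Present signals of 29.4 to 36.8. *E(spl)m4-BFM* has means of 2353 and 236, while *E(spl)mbeta-HLH* has means of 8826 and 8819.

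Across the array, 148 of the 4943 tested probe sets changed (limma, adjusted p under 0.05), of which 62 were higher in GFP-positive cells and 86 lower. They covered 54 higher and 72 lower named genes, and 60 of the higher and 79 of the lower probe sets changed at least 2-fold. At an unadjusted p under 0.05 there were 690 probe sets. The groups did not overlap in any of the 148, and they did not overlap in 20.8% of all tested probe sets, where chance gives 10%. Beside the genes above, the 10 highest included *Rsph3*, a radial spoke protein gene of motile cilia (at least 24.0-fold, adjusted p = 6.68e-06), *peb*, a zinc finger transcription factor (at least 10.3-fold, adjusted p = 0.00165), and *ktub*, a tubby-family gene (at least 9.17-fold, adjusted p = 0.000843). They also included *qua*, a villin-like actin-bundling protein (at least 5.43-fold, adjusted p = 0.00117), the receptor tyrosine kinase gene *Ror* (log2 2.76, SE 0.247, adjusted p = 0.000271) and *Ect3*, whose signal rose from 645 ± 34.1 to 7364 ± 269 (adjusted p = 1.24e-05). The 10 lowest included *Mal-A5*, a maltase gene (at least 10.7-fold lower, adjusted p = 0.000244), *CG9593* (at least 12.2-fold lower, adjusted p = 0.000337), *MFS14*, a transporter gene (log2 -2.21, SE 0.263, adjusted p = 0.00154), and *eya*, a transcriptional coactivator and phosphatase (at least 3.95-fold lower, adjusted p = 0.0186).

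The number of probe sets changed rose to 257 (107 higher, 150 lower) with replicate number as a block, and all 148 were among them. With hybridization day as a block it was 229, again with all 148, and with lot as a block 132, of which 109 were shared. It was 76 in the 4 arrays of day 2. The day 1 pair and the lot of 2 arrays allow no test, and the lot of 3 arrays, with 1 GFP-positive array, leaves 1 residual degree of freedom, so its p-values decide no call of a gene or list here. All 148 had the same sign in each of the 3, but this was fixed in advance, since the groups overlapped in none of the 148. Leaving out an array gave 69 without GFP-negative replicate 2, 98 without GFP-negative replicate 3, 78 without GFP-positive replicate 1 and 84 without GFP-positive replicate 3. Of the 20 largest changes named by rule, 16 were called whichever array was left out, and the others were *eya*, *CG7737*, *CG8192* and *trol*. The call of *eya* was lost without GFP-negative replicate 2 (adjusted p = 0.0935) or 3 (0.0679) and without GFP-positive replicate 1 (0.0701) or 2 (0.0604). The call of *CG7737* was lost without GFP-negative replicate 2 (0.0501) or GFP-positive replicate 3 (0.0508), and that of *CG8192* without GFP-negative replicate 2 (0.0564) or GFP-positive replicate 1 (0.0591). In the day 2 arrays these 3 had adjusted p-values of 0.0646, 0.0868 and 0.0772, and with no filter 0.0726, 0.052 and 0.0717. The call of *trol* was also lost with no filter (0.0889).

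Some genes of the adult muscle precursors, the mesodermal myoblasts that lie on the notum epithelium, were lower in GFP-positive cells (3 of 6 tested). *Him*, an inhibitor of muscle differentiation, was at least 13.2-fold lower (adjusted p = 0.000134), and *htl*, a fibroblast growth factor receptor of mesoderm, at least 8.38-fold lower (adjusted p = 0.000271). *SPARC*, a collagen-binding protein of basement membranes, was at least 14.9-fold lower (adjusted p = 0.00143), though only 2 of the 3 GFP-negative arrays called it Present. *Mes2*, another gene known from mesoderm and one of the 10 lowest, was at least 5.17-fold lower (adjusted p = 0.00455). Of the 6 tested genes of the myoblast list, 3 fell, 0 rose and 3 did not pass, and adjusted over the list alone 5 were lower. *Him*, *htl* and *SPARC* were tested only because the GFP-negative arrays detected them, which favours members that fell. The list had a median of -1.97 (-1.91 with undetected members at their bound, -0.75 with no filter) and a camera adjusted p = 5.16e-06, but adjusted p = 0.103 with an estimated correlation. *Ama*, which the disc epithelium can also express, had a log2 difference of -0.50 (adjusted p = 0.268), *if* had -0.75 (adjusted p = 0.285), *sns* had 0.53 in the other direction (adjusted p = 0.36), and *twi* and *zfh1* were Present on no array.

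All 3 genes of the posterior compartment list fell. *en* and *inv* are the neighbouring homeobox genes that specify posterior identity. *en* had a log2 difference of -2.13 (SE 0.258, adjusted p = 0.00165), *inv* was at least 4.07-fold lower (adjusted p = 0.00165) and the signalling gene *hh* at least 2.80-fold lower (adjusted p = 0.0334). The signal of *en* was 691 ± 195 (SD, n = 3) in GFP-positive and 3007 ± 382 in GFP-negative cells. The camera adjusted p was 3.76e-06, but adjusted p = 0.103 with an estimated correlation. *inv* and *hh* were tested only because the GFP-negative arrays detected them, which favours members that fell, while *en* was Present on all 6 arrays. The call of *hh* was lost without any 1 of the 6 arrays, with adjusted p-values of 0.107, 0.151 and 0.0828 without GFP-negative replicates 1, 2 and 3 and of 0.0952, 0.0708 and 0.0516 without GFP-positive replicates 1, 2 and 3. It was also lost with lot as a block (0.112), with no filter (0.092) and in the day 2 arrays (0.174). The anterior gene *ci* had a log2 difference of 0.11 (95% interval -0.39 to 0.60). The notum list had 6 tested genes, of which 2 fell, 0 rose and 4 did not pass, with the same count of 2 adjusted over the list alone. The 2 were the homeobox genes *B-H1* (at least 3.80-fold lower, adjusted p = 0.00339, Present on 2 of the 3 GFP-negative arrays), which patterns the anterior notum, and *dve* (log2 -1.61, adjusted p = 0.00573), which is better known from the wing pouch. The call of *dve* was lost in the day 2 arrays (adjusted p = 0.0509). The notum list had a median of -0.63 and a camera adjusted p = 2e-04, but adjusted p = 0.26 with an estimated correlation. Its member *B-H1* was likewise tested only because the GFP-negative arrays detected it.

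**Figure D3:**
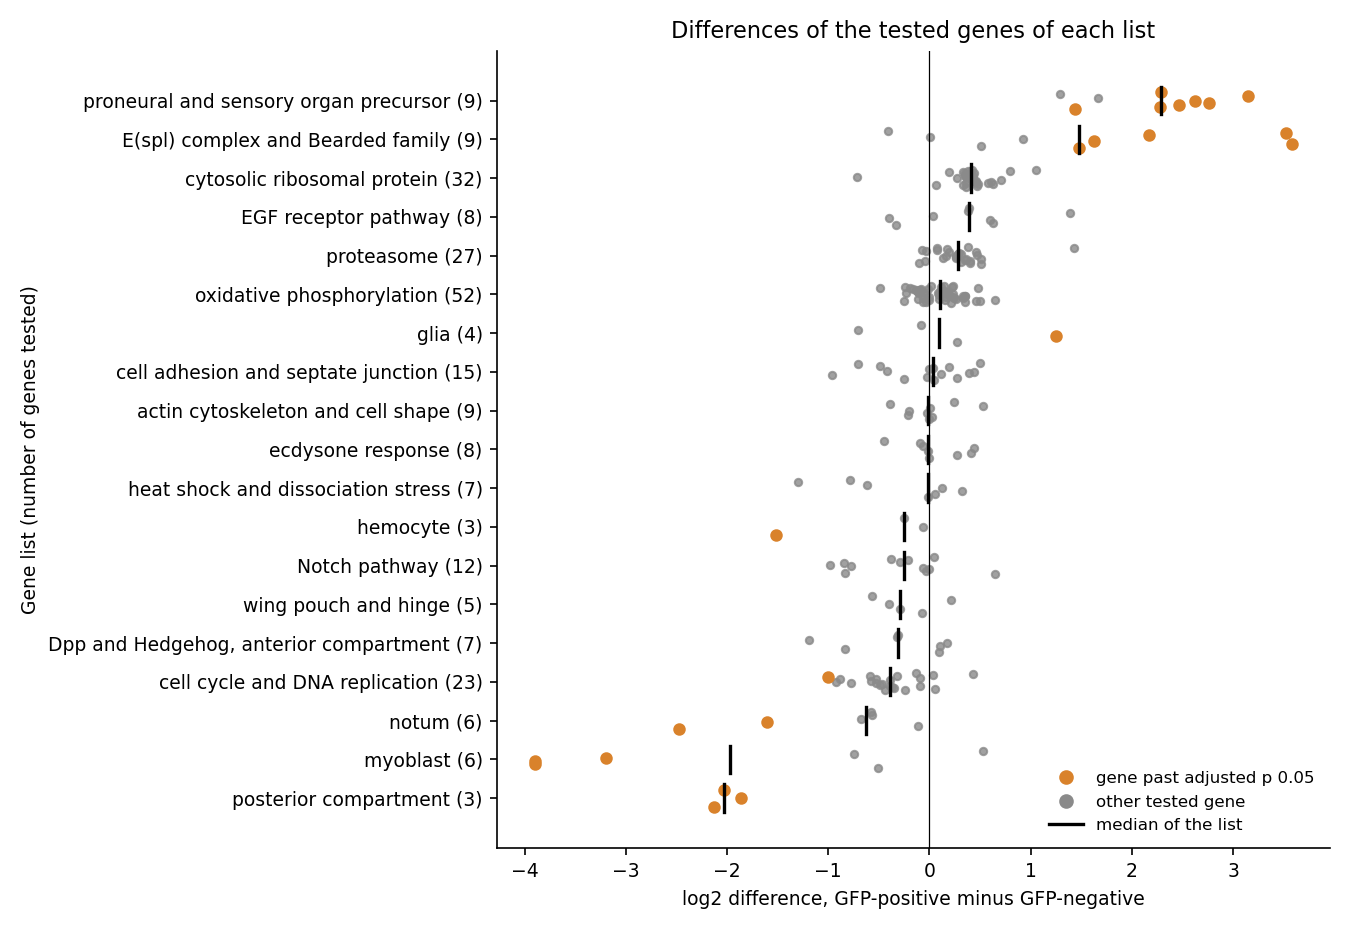
Log2 difference (GFP-positive minus GFP-negative) of each tested gene of the 19 lists; each point is a gene, orange points passed an adjusted p of 0.05, black bars are list medians, and the number of tested genes stands in parentheses. The proneural list has a median of 2.29, the E(spl) and Bearded list 1.48, the myoblast list -1.97 and the posterior list -2.03.

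Of 23 tested genes of the cell cycle and DNA replication, 1 fell, 0 rose and 22 did not pass, while 20 had a negative sign. The 1 was the replication helicase gene *dpa*, with signals of 967.5 ± 195 in GFP-positive and 1928 ± 159 in GFP-negative cells (SD, n = 3; limma adjusted p = 0.0448). Adjusted over the list alone, 4 were lower. *RnrL*, a subunit of ribonucleotide reductase, had a log2 difference of -0.89 (adjusted p = 0.0553, or 0.0223 with the replicate block and 0.0281 with the day block), *Mcm5* of -0.78 (adjusted p = 0.147, or 0.0483 with the replicate block and 0.0372 with the day block), and *Orc1*, Present on no GFP-positive array, had a bound of 1.90-fold lower (adjusted p = 0.067, or 0.046 without an intensity trend and just under the threshold of 0.05 with quantile scaling). The list's median was -0.39 and its camera adjusted p = 0.000206, but adjusted p = 0.122 with an estimated correlation. The call of *dpa* was lost under quantile (adjusted p = 0.0552) and median scaling (0.0538), and without GFP-negative replicate 2 (0.216) or 3 (0.128) or GFP-positive replicate 1 (0.167), 2 (0.0845) or 3 (0.065). It was also lost with lot as a block (0.0675), with no filter (0.081), without an intensity trend (0.0551) and in the day 2 arrays (0.131).

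None of the 32 tested cytosolic ribosomal protein genes passed the limma threshold, over all genes or adjusted over the list alone, but 31 had a positive sign with a median of 0.41, and 5 had an unadjusted p under 0.05. The list's camera adjusted p was 3.54e-07, but adjusted p = 0.471 with an estimated correlation and 0.291 by fry. Under quantile scaling its median was 0.06 and the call was lost (adjusted p = 0.0706), and its median was 0.24 in the day 2 arrays (adjusted p = 0.00373) and without GFP-negative replicate 1 (0.00218). Of the 27 tested proteasome genes, 0 passed, over all genes or adjusted over the list alone, with a median of 0.28 and 1 gene at an unadjusted p under 0.05. *Rpt3R* had the smallest p of these genes (a bound of 2.64-fold, adjusted p = 0.0982, or 0.0422 with the replicate block). The proteasome list had a camera adjusted p = 0.000467, but adjusted p = 0.376 with an estimated correlation, and its call was also lost with no filter (adjusted p = 0.0958) and by fry (0.183). All 8 lists that passed camera also did so with day or lot as a block and in the day 2 arrays. In the day 2 arrays the medians were 2.29 for the proneural list, 1.34 for the E(spl) and Bearded list, -1.98 for the posterior list and -2.12 for the myoblast list. In the lot of 3 arrays, without a test, the medians of the 8 lists were 2.55 (proneural), 1.09 (E(spl) and Bearded), -1.91 (posterior), -1.91 (myoblast), -0.80 (notum), -0.35 (cell cycle), 0.52 (ribosomal) and 0.37 (proteasome).

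The other 11 lists did not pass. Adjusted over the list alone, 1 gene was lower in each of the Notch, Dpp and Hedgehog, hemocyte, glial and cell adhesion lists. By the same adjustment 1 gene was higher in each of the EGF receptor and glial lists. Of 12 tested Notch pathway genes 0 passed in limma and 4 had an unadjusted p under 0.05 (median -0.25, camera adjusted p = 0.182). The ligand gene *Delta* had a log2 difference of 0.65 (adjusted p = 0.192) and the glycosyltransferase gene *fng* of -0.84 (adjusted p = 0.067, or 0.0319 with the replicate block and 0.0286 with the day block). This list had an adjusted p of 0.0406 with no filter, 0.00685 with lot as a block and 0.0055 without GFP-positive replicate 2, the array that was alone in its lot. Of 8 tested EGF receptor pathway genes 0 passed, 2 had an unadjusted p under 0.05, and 1 was higher adjusted over the list alone (median 0.39, camera adjusted p = 0.138). The pathway gene *edl* had a log2 difference of 1.39 (adjusted p = 0.0548, or 0.00956 with the replicate block, 0.0176 with the day block, 0.0483 with an offset of 64 and 0.0456 under median scaling). The EGF receptor list passed without GFP-negative replicate 1 (adjusted p = 0.0383) or GFP-positive replicate 3 (0.0192). Of 7 tested Dpp and Hedgehog genes 0 passed and 1 had an unadjusted p under 0.05 (median -0.31, adjusted p = 0.246, or 0.049 without GFP-positive replicate 2), and *kn* had a log2 difference of -1.19 (adjusted p = 0.0894). *Mad* had -0.84 (limma adjusted p = 0.393). It passed with lot as a block (-1.37, adjusted p = 0.0357) and without GFP-positive replicate 2 (-1.36, adjusted p = 0.0336). Of 52 tested genes of oxidative phosphorylation 0 passed, with 0 at an unadjusted p under 0.05 (median 0.10, adjusted p = 0.182, but 0.000696 without GFP-negative replicate 3 and 0.0119 without GFP-positive replicate 2).

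Lists of other cell types and of cell handling gave few calls. Of 3 tested hemocyte genes, *Col4a1*, a collagen of basement membranes, fell (at least 2.86-fold, adjusted p = 0.00696), and the blood cell genes *crq* and *srp* had differences of -0.07 and -0.25 (list adjusted p = 0.138, but 0.004 by fry and 0.0492 with no filter). The call of *Col4a1* was lost without GFP-negative replicate 2 (adjusted p = 0.0544). Of 4 tested glial genes, *loco*, a regulator of G protein signalling, rose (at least 2.38-fold, adjusted p = 0.0297, Present on 2 of the 3 GFP-positive arrays), while *repo*, which marks glia, had -0.09 (adjusted p = 0.937, list adjusted p = 0.65). The call of *loco* was lost with lot as a block (adjusted p = 0.0871), with no filter (0.081), in the day 2 arrays (0.174), without GFP-negative replicate 1 (0.0594) or 2 (0.151) and without GFP-positive replicate 1 (0.13), 2 (0.0824) or 3 (0.0592). Of 7 tested genes of heat shock and dissociation stress 0 passed and 2 had an unadjusted p under 0.05 (median -0.01, list adjusted p = 0.424). The same held for 5 genes of the wing pouch and hinge (median -0.29, list adjusted p = 0.417), 8 of the ecdysone response (-0.01, 0.712), 15 of cell adhesion and septate junctions (0.04, 0.712) and 9 of the actin cytoskeleton (-0.01, 0.938). Of these 4 groups, 2 adhesion genes and 0 of the others had an unadjusted p under 0.05. The adhesion gene *Nrx-IV* had a log2 difference of -0.96 (adjusted p = 0.0677, or 0.0222 with the replicate block, 0.022 with the day block and 0.0472 with the lot block). Lists of Wingless signalling, trachea, fat body and neurons had fewer than 3 tested genes and were not tested.

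Detection calls, which do not depend on the scaling between arrays, gave 22 probe sets Present on all GFP-positive and Absent on all GFP-negative arrays, and 45 with the reverse. With Absent or Marginal in place of Absent the counts were 32 and 89.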

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

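The tests of hybridization day and of 5′ sequence loss, the block for day, and the splits by replicate pair were chosen only after the arrays of replicate 1 had been seen to stand apart. The other tests were fixed before their results were seen, apart from conditions that the tests as first written did not hold. These were the conditions on the intervals of *Ama*, of the blood-cell genes, of *hh* and of *ci*, and the rule that 10 splits are too few to decide.

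Control probe sets stayed outside the comparison of genes. Of 44 such probe sets, 20 were Present on all GFP-positive arrays, and in 3 of these every GFP-positive array lay above every GFP-negative array, where chance gives a share of 5%. Among all tested probe sets the groups did not overlap, in either direction, in 20.8%, so 3 of 20 does not stand out clearly. The 3′ probe set of actin had a mean of 31063 in GFP-positive and 27794 in GFP-negative cells (SD 1050 and 1710, n = 3), that of GAPDH 30436 and 21864 (SD 2770 and 3280), and that of eIF-4a 48935 and 39073 (SD 3160 and 2230). No explanation was tested for them.

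The myoblast genes *Him*, *htl* and *SPARC* were lower in GFP-positive cells. Scaling between arrays is argued against, because the list's median stayed at -1.93 or lower under 3 scalings. Fewer myoblasts in the GFP-positive sort predicted a median below -0.5 for the other tested members, and *Ama*, *if* and *sns* had a median of -0.504, just past it, but the interval of *Ama*, the middle gene, ran from -0.94 to -0.07 and *sns* had 0.53 in the other direction, which leaves it open. Blood cells in the GFP-negative sort were to be argued against by a median above -0.2, and *crq* and *srp* had -0.16, but they also stay open, since that lay past the bound by less than the spread (interval -0.76 to 0.62 for *crq* and -1.42 to 0.93 for *srp*), while the other 7 of 9 blood-cell genes looked for, such as *Hml*, *NimC1* and *eater*, were Present on no array and *Col4a1*, a collagen gene of the hemocyte list outside this test, fell at least 2.86-fold. A lower share of myoblasts among reporter-expressing epithelial cells is thus a candidate explanation that these tests cannot separate from lower expression within the cells.

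The posterior genes *en*, *inv* and *hh* were lower in GFP-positive cells. Scaling between arrays is argued against, because the mean of *en* and *inv* stayed at -2.04 or lower under 3 scalings. Fewer posterior cells in the GFP-positive sort predicted a fall of *hh* and a rise of anterior genes above 0.2, and *hh* was at least 2.80-fold lower but *ci*, the anterior gene tested, had 0.11 with an interval of -0.39 to 0.60. A lower share of posterior cells and a lower level of these genes within cells therefore cannot be told apart here.

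Replicate 1 of both groups lay apart on the second principal component (25.5 in GFP-negative, 13.9 in GFP-positive, against -19.3 to -4.3). Across whole profiles only GFP-negative replicate 1 did so. It correlated at 0.949 and 0.925 with replicates 2 and 3, which correlated at 0.975 with each other. GFP-positive replicate 1 correlated at 0.956 and 0.959 with its group's other arrays, against 0.95 between those. The arrays of replicate 1 deviated together from their group means, with a correlation of 0.402 across tested probe sets. Day 1 held only these arrays, so an effect of hybridization day and a difference between the samples of replicate 1, which was not tested, cannot be told apart. Loss of 5′ sequence on day 1 was tested on 3 messenger RNAs and came out against it, since the 5′ over 3′ ratio lay below the day 2 range on both day 1 arrays for 1, GAPDH, and inside it for actin and eIF-4a. It stays open because 18S ribosomal RNA, which the test did not include, also lay below that range (0.95% and 1.07% against 1.76% to 4.1%). On all 6 arrays the ratios of the messenger RNAs were low, at 1.37% to 4.91% for actin, 2.34% to 5.81% for GAPDH and 0.56% to 3.5% for eIF-4a. Probe sets far from the 3′ end may therefore read Absent on every array, so Present on no array does not show that a gene was unexpressed.

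The 148 probe sets changed between the groups were set beside the other splits of the 6 arrays into groups of 3. Of the 10 splits, 1, the real one, gave as many, and the highest of the others gave 0 changed probe sets by limma, with up to 490 at an unadjusted p under 0.05 against 690 in the real split. With 10 splits no share under 0.05 is possible. Every other split also puts arrays of both groups on each side. The difference between the groups then adds to the spread within its sides and lowers its calls. The other splits therefore cannot show how many calls would arise without a difference between the groups. These splits ignore the replicate numbers, whose pairing the data do not establish. Of the 4 that part all 3 pairs, as the real one does, the other 3 gave 0 changed probe sets with and without the replicate block, where the real split gave 257 and 148, and at an unadjusted p under 0.05 they gave at most 122 and 136 against 884 and 690. The 6 remaining splits part 1 pair and keep the others together. For detection switches the real split gave 67 and the highest other 19.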

How the results depend on the processing

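The block for hybridization day, the day 2 arrays alone, the lot of 3 arrays alone and the replicate block with a fold of at least 2 were chosen only after the data were seen. No result past its threshold reversed its direction under any alternative that gave a value. For the 148 probe sets this was fixed in advance wherever arrays were left out, because their groups did not overlap. Against 148 probe sets changed (62 higher, 86 lower), no filter gave 97 changed and 44 lower, and Present on all 6 arrays gave 50 (21 higher, 29 lower) and 5 lists in place of 8, from fewer probe sets tested. The replicate block gave 257 (107 higher, 150 lower) and changed the call of 9 named genes, each to pass, and of no list. The block for day gave 229 changed and 137 lower, the day 2 arrays 76 (41 higher, 35 lower), and the lot of 3 arrays, with 1 residual degree of freedom, 84 (33 higher, 51 lower), from fewer arrays. Leaving out each array gave 69 to 153 changed, 36 to 69 higher and 33 to 84 lower, and 8 to 11 lists. Camera with an estimated correlation passed 0 lists, with adjusted p-values of 0.0888 and above, where fry passed 7. With Absent or Marginal in place of Absent, 89 probe sets in place of 45 were Present in GFP-negative cells alone. Of the 101 named genes, no filter and the day 2 arrays each lost 11 calls, and the lot block lost 5 and gained 2. With an offset of 64 the fitted log2 differences of 6 dim genes shrank by over 1.5 times and all 6 still passed, such as *qua* (3.26 to 2.05) and *hh* (-1.86 to -1.12). The cause of these shifts was not tested otherwise. Offsets, scalings, the intensity trend, the lot block and the fold limit gave 132 to 156 changed, and the series table moved nothing. A lone array in a group was assumed to vary like the other group. Signals near the lowest Present level, 29.4 to 36.8 units, limit what can be said of dim genes.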

Other observations

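The lists of ciliary, basement membrane and glutathione S-transferase genes below were chosen only after some of their members had been seen to change, as was the rule that the interval of the middle basement membrane or ciliary gene had to clear its bound.

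Some genes of the basement membrane and of collagen processing, chosen after their values were seen, were lower in GFP-positive cells. Of 12 tested genes, 7 fell and 0 rose (limma, adjusted p under 0.05), with a median of -1.44, while *wb* (0.07) and *PH4alphaEFB* (0.40) had positive differences that did not pass. The 7 were *SPARC*, *trol*, *Col4a1*, *Ppn*, *Mp*, *Plod* and *Timp*, with *SPARC* also in the myoblast list and *Col4a1* in the hemocyte list. Of these, *SPARC*, *trol*, *Col4a1*, *Mp* and *Timp* passed the detection filter through the GFP-negative arrays alone, which favours members that fell. *trol*, the fly's perlecan, was Present on no GFP-positive array, and its fitted log2 difference was -2.19 (adjusted p = 0.0247, but 0.0889 with no filter, 0.0898 without GFP-negative replicate 2, 0.0641 without GFP-negative replicate 3 and 0.0544 without GFP-positive replicate 2). *Ppn*, papilin, had signals of 902 ± 197 and 2712 ± 452 (SD, n = 3; log2 -1.58, adjusted p = 0.00587), and *Plod*, a lysyl hydroxylase of collagen, had 1162 ± 358 and 2951 ± 449 (log2 -1.37, adjusted p = 0.0237).

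Some glutathione S-transferase genes, which detoxify reactive compounds, were higher. Of 17 tested, 3 rose and 0 fell, with a median of 0.40. *GstZ2* was at least 6.15-fold higher (adjusted p = 0.00102), *GstO1* had a log2 difference of 1.38 (adjusted p = 0.0123) and *GstE1* of 1.31 (adjusted p = 0.00609), while *GstD1* had 0.18 (adjusted p = 0.791). The group was named from these members, so no list test is given.

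One hypothesis was that the lower basement membrane genes reflect a change shared by the whole gene group. Its test used the 5 members whose values had not been seen, *LanA*, *LanB1*, *LanB2*, *wb* and *PH4alphaEFB*, and predicted a median below -0.5. The median was -0.69, past that bound, but the interval of its middle gene *LanA* ran from -1.34 to -0.04, and 0 of the 5 passed the limma threshold while 3 had an unadjusted p under 0.05. Camera gave p = 0.0839 for these genes (0.367 with an estimated correlation). A shared change may exist and was not settled by these genes.

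Another hypothesis was that GFP-positive cells carry a program for the sensory cilium, since *Rsph3*, *ktub* and *Oseg6* were higher. Its test used 54 other ciliary genes, of which 36 were on the array and only 5 were tested. Their median was 0.47, with 4 positive and 1 negative. That median and the camera p of 0.0236 met the bounds of 0.3 and 0.05 set beforehand, but the interval of the middle gene *Oseg5* ran from -0.08 to 1.01, so the hypothesis stays open. *dnd*, *Oseg5* and *Oseg4* passed the detection filter through the GFP-positive arrays alone, which favours members that rose and a positive median. *Oseg1* and *IFT43*, Present on all arrays of both groups, had log2 differences of 0.35 and -0.37. In limma, 0 of the 5 passed the threshold over all genes, 2 had an unadjusted p under 0.05, and *dnd* alone (a bound of 2.99-fold, adjusted p = 0.0631) passed when adjusted over the list alone. With an estimated correlation, camera gave p = 0.0822.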
